A study of Mus musculus with 27 samples.

How the data were processed

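Messenger RNA was measured in 27 mouse libraries: 3 tissues (brain, meninges, skull) by 3 groups (untreated control, 0.5 h and 24 h after UVB at 311 nm and 2 mW on the interparietal bone), with 3 libraries in each of 9 groups. Per the labels, the skullcap was rinsed of blood in cold PBS, the meninges were scraped from it into cold RNAlater, RNA was extracted with TRIzol and poly(A) RNA was isolated with magnetic beads before Illumina library preparation. The deposited values are counts per gene symbol, whole numbers with a different total in each library. Per the submitters' processing notes, HISAT2 2.1.0 and the mm10 build were used. The counting tool, its annotation and its strand setting are not given in the sources used here. With the strand setting unknown, reads over exons that 2 genes share may have been counted for either, so exon overlaps are printed beside Rbm3, Atcayos and Prg4. Other named genes share exon bases too without a mention beside them, such as Dbp (1585 bases with Sphk2 on the opposite strand). The key that came with the count table matched the labels for all 27 columns.

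Coordinates, GC content and transcript length come from GENCODE M21 on GRCm38 (mm10), to which 33437 of 37095 symbols (90.1%) were matched. Totals ran from 14.2 M to 27.3 M counts. SD and SE printed with levels and log2 fold changes hold the spread between libraries. Each SE of a log2 fold change was worked back from its test. It is the absolute log2 fold change over the square root of the edgeR F statistic, whose dispersion draws on all groups of the fit. Intervals of ratios of counts (95%, exact Clopper-Pearson), used where a group had 1 to 3 counts, and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Fitted fold changes of genes with a group at 0 are printed as bounds against a floor of 3 counts over the group.

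Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (robust option) in R 4.3.3, with TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15). Each tissue was fitted from its 9 libraries, and 0.5 h against control, 24 h against control and 24 h against 0.5 h were tested. Differences of the effect between tissues were tested in a fit of all 27 libraries. P-values were adjusted by Benjamini and Hochberg's method over all tested genes of a comparison at 0.05. Each gene's level is given as CPM, counts scaled to library size, on TMM-scaled totals, except for tissue markers and single libraries, which use plain totals. Before the data were examined, 54 gene lists (pathways and cell type markers, 1171 entries, 1107 distinct genes, 14 entries without a match) were fixed with the groups, tests, alternatives and the rule for named genes. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with an estimated correlation and with fry as alternatives. List counts are given over all tested genes and, as "over the list alone", with adjustment over the members only.

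Genes named by size are, in each comparison with control, the 8 with the largest positive and the 8 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 1 CPM over the tissue, an established symbol, and all 3 libraries of each group on their own side. For 24 h against 0.5 h and for differences between tissues 5 and 5 were taken, the last without the condition on libraries. Some genes that met the rule are not reported here. Other genes are the members of a list with the smallest p, or were named after their values were seen: the clock genes Npas2 and Dbp as a pair with their list, Rbm3, Cirbp, and the genes called in all 3 tissues. Where fewer than 10 genes met the rule in a comparison within a tissue, the 6 with the smallest p that did not pass are given too.

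Alternatives fixed with the plan were RLE scaling, scaling without haemoglobin and mitochondrial genes, no filter, no robust option, limma-voom with quality weights, DESeq2 1.42.0, a fit of the 2 groups alone, a fit of all 27 libraries, replicate numbers as a block, and leaving out each library. A library left out also takes a replicate from the fit. Counts may fall and calls may end from lost power alone, so they do not by themselves mark a library as unusual. Chosen after seeing the data were a correction for GC content and transcript length (covering 95.9%, 95.8% and 95.9% of tested genes in brain, meninges and skull) and thinning brain control 1 to the median total of the other brain libraries. Labels were also exchanged: each comparison within a tissue was rerun for the 10 splits of its 6 libraries, and each difference between tissues for 40 drawn regroupings.

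The test was tested on simulated data with the means and spread of these libraries. Of genes changed 2-fold, 70.1% were called in brain, 62.5% in meninges, 68.1% in skull and 48% for the difference of skull and brain. At 4-fold these were 90.3%, 81.2%, 84.4% and 74.3%, and at 1.5-fold 39%, 11.1%, 32.5% and 13.6%. Of the calls 5.15%, 7.76%, 9.85% and 4.12% were genes that had not been changed. A simulated list shifted 1.5-fold was called in meninges and skull (adjusted p = 3.4e-13 and 1.4e-20) but not in brain (0.33), with 0 other lists called. The simulated genes were drawn independently of each other, so this does not test camera where genes vary together. In the real skull libraries of control and 0.5 h, another split of the labels passed 28 lists. No 2 libraries had counts as close as technical repeats of 1 sample would (chi-square per degree of freedom 5.14 to 56.7). No library was left out.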

Results

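RNA was counted in 27 mouse libraries from the brain, the meninges scraped from the skullcap, and the skullcap itself, called skull below. In each tissue 3 libraries came from untreated mice (control), 3 from mice 0.5 h and 3 from mice 24 h after UVB light was shone on the interparietal bone, a bone of the rear skullcap. The series asks how light on the cranium acts on immunity at the borders of the brain and on stroke recovery. No library here is labelled with stroke, and non-cranial irradiation, which the design text also names, was not analysed here. The labels do not say whether the controls were sham-handled, at what clock time any group was collected, or whether replicates came from separate animals, so each p-value measures only the spread between these samples. Library totals ran from 14.2 M to 27.3 M counts. Brain control 1 was the deepest and the next held 18.2 M.

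Markers of the 3 tissues separated as dissected. The median level of neuron markers was 504 ± 13 CPM (counts scaled to library size, mean ± SD of 3 control libraries) in brain, 38.7 ± 25.1 in meninges and 3.94 ± 0.387 in skull. Markers of meningeal fibroblasts stood at 80 ± 6.91 CPM in meninges and 16.7 in skull. Those of osteoblasts stood at 94.2 ± 22.9 and 185 ± 41.5, and those of mature neutrophils at 13.5 and 190 ± 72.8, so the skull pieces held marrow and the meninges some bone. Pineal markers stood at 82.3 ± 12 CPM in meninges, 0.272 in brain and 0.426 in skull. Some libraries carried markers of neighbouring tissue. Ttr, the transthyretin of choroid plexus, ran from 6.53 CPM (meninges control 1) to 13900 CPM (meninges 24 h 1), and the skeletal muscle actin Acta1 from 2.24 to 1030 CPM across the meninges. Brain control 1 held Cd74, of antigen-presenting cells, at 25.1 CPM against 2.21 and 2.42 in the other brain controls, and the skin keratin Krt14 at 4.87 CPM, where the other brain controls list 0.

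In the brain 0.5 h after irradiation, Per1, a repressor of the circadian clock that glucocorticoids and neuronal activity also induce, fell from 127 ± 12.7 to 80.1 ± 2.98 CPM (log2 fold change −0.66 ± 0.08, ± SE throughout, adjusted p = 0.00439, n = 3 and 3, chromosome 11, 69095217 to 69109960, plus strand). Glucocorticoid targets had a median of −0.38: 1 of 22 measured members fell (camera adjusted p = 2.1e-14, adjusted p = 0.026 with an estimated correlation), and 6 were lower when adjusted over the list alone. Clock genes had a median of −0.15 with 1 of 20 lower, again Per1 (camera adjusted p = 9.7e-08, adjusted p = 0.026 with an estimated correlation). Members of these lists that did not pass were Sgk1 at −0.59, Cdkn1a at −0.86 and Ciart at −0.72. Immediate early genes (median −0.30, 0 of 31 passing, 1 lower over the list alone) and ribosomal protein genes (median −0.22, 0 of 67) also passed camera, at 9.7e-08 and 9.4e-11 (adjusted p = 0.41 and 0.51 with an estimated correlation). Without brain control 1 the ribosomal protein genes did not pass camera (median −0.05, adjusted p = 0.15). The other 3 lists passed with smaller shifts. Medians were −0.22 for glucocorticoid targets (camera adjusted p = 6.2e-09), −0.12 for clock genes (3.1e-07) and −0.17 for immediate early genes (0.012). With an estimated correlation their adjusted p was 0.043, 0.043 and 0.8.

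Per1 was the 1 gene of 18172 that edgeR called in the brain at 0.5 h. In all 955 had an unadjusted p under 0.05 and 11.5% had groups that do not overlap, against 10% from chance. DESeq2 called 14 genes and limma-voom 1. The genes next in order of p were Utp14b (−0.64, adjusted p = 0.14), Polr3e (−0.47, 0.14), Txnip (−0.77, 0.159), Rpl13a (−1.35, 0.159), Zfp84 (0.72, 0.176) and Errfi1 (−0.62, 0.311); none passed. The call of Per1 ended without control 3 (adjusted p = 0.0693), 0.5 h 1 (0.0508) or 0.5 h 2 (0.125), with a count of 0 in each case. The count was 9 without control 2 and 3 without 0.5 h 3. Of 52 lists 13 passed camera, 7 without control 1, and 2 passed with an estimated correlation.

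In the brain 24 h after irradiation, Cdkn1a, a cell cycle inhibitor that glucocorticoids induce, fell by 1.80 ± 0.19 (log2, 32 ± 8.86 to 9.2 ± 1.81 CPM, adjusted p = 0.000226, n = 3 and 3). The kinase Sgk1 stood at −1.46 ± 0.15 (0.00156) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at −0.56 ± 0.08 (0.00211). Per1 stood at −0.55 ± 0.08 (0.00227). Of 22 measured targets 6 fell and 0 rose, with 13 lower over the list alone (median −0.58, camera adjusted p = 7.6e-15, adjusted p = 0.065 with an estimated correlation). Immediate early genes fell in 2 of 31 cases (4 lower and 1 higher over the list alone, median −0.31, camera adjusted p = 0.0021, adjusted p = 0.67 with an estimated correlation). Fos of this list stood apart in 24 h 1, at 96.5 CPM against 20 and 20.7 CPM in the other 24 h libraries. Without brain control 1 the list did not pass camera (1 of 31 lower, median −0.08, adjusted p = 0.054), while 7 of 22 glucocorticoid targets were lower (median −0.55, camera adjusted p = 3e-13, adjusted p = 0.018 with an estimated correlation). The clock gene Nr1d2 rose by 0.36 ± 0.07 (0.00829), 1 of 20 clock genes to rise and Per1 1 to fall (camera adjusted p = 0.32). Rbm3, a cold-inducible RNA-binding protein, rose by 0.77 ± 0.11 (0.0013, chromosome X, 8138975 to 8145880, minus strand, sharing 614 exon bases with Rbm3os on the opposite strand).

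Chaperones fell in 6 of 25 cases (13 over the list alone, median −0.41, camera adjusted p = 2.9e-12, adjusted p = 0.17 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, stood at −0.73 ± 0.09 (adjusted p = 0.000281) and Xbp1, a regulator of the same compartment, at −0.52 ± 0.09 (0.00401). Nuclear genes of oxidative phosphorylation fell in 8 of 74 cases (32 over the list alone, median −0.28, camera adjusted p = 2e-15, adjusted p = 0.5 with an estimated correlation). Ndufa12 of complex I is among them at −0.77 ± 0.14 (0.00829). Ribosomal protein genes fell in 3 of 67 cases (20 over the list alone, median −0.45, camera adjusted p = 6.4e-17, adjusted p = 0.5 with an estimated correlation). Cell cycle genes fell in 3 of 37 cases (8 over the list alone, median −0.72, camera adjusted p = 3.7e-07, adjusted p = 0.5 with an estimated correlation). Mki67, a proliferation marker, stood at −1.57 ± 0.29 and the mitotic kinase Cdk1 at −4.15 ± 0.75. Both calls ended without brain control 1 (adjusted p = 0.0521 and 0.0762), the library with raised Cd74 and Krt14. Interferon-stimulated genes had a median of −1.30 with 0 of 38 passing (camera adjusted p = 1.2e-09, adjusted p = 0.5 with an estimated correlation). Their mean log2 level was 2.89, 1.57 and 3.18 in the 3 controls and 1.41, 1.29 and 1.85 at 24 h, so the controls differed among themselves by about as much. Without brain control 1 the members called lower were 2 of 25 chaperones (median −0.28, camera adjusted p = 1.6e-11, adjusted p = 0.22 with an estimated correlation) and 1 of 74 genes of oxidative phosphorylation (−0.21, 1.1e-10, adjusted p = 0.64 with an estimated correlation). Ribosomal protein genes (0 of 67, −0.27, 1.1e-10), cell cycle genes (0 of 37, −0.31, 0.0064) and interferon-stimulated genes (0 of 38, −1.0, 1.5e-08) had no member called without that library (adjusted p = 0.64, 0.64 and 0.65 with an estimated correlation).

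By size, the genes that rose most in brain at 24 h were Atcayos (2.31 ± 0.41), Zfp418 (2.24 ± 0.36), Dnase1l2 (1.86 ± 0.38), Actl10 (1.56 ± 0.30), the nicotinic receptor subunit Chrna3 (1.56 ± 0.37), Osr1 (1.46 ± 0.37), Tmem170 (1.26 ± 0.27) and the death receptor Tnfrsf25 (1.24 ± 0.24). Those that fell most, after Cdk1, were Depp1 (−3.50 ± 0.51), the basic leucine zipper factor Maff (−3.21 ± 0.41), the chromatin protein Hmgb2 (−2.64 ± 0.26), Apold1, an early gene of endothelium (−2.39 ± 0.28), Foxf1 (−2.39 ± 0.48), the leukotriene receptor Cysltr2 (−2.29 ± 0.50) and Rhbdf2 (−2.07 ± 0.50). Atcayos shares 524 exon bases with Atcay and 270 with Nmrk2 on the opposite strand. Of these 16 genes named by size, Atcayos, Zfp418, Depp1, Maff, Hmgb2 and Apold1 kept the call whichever of the 9 brain libraries was left out. The other 10 lost it without brain control 1, at adjusted p up to 0.195 (Rhbdf2). Further libraries that ended calls were control 2 (Foxf1, 0.0517), control 3 (Tmem170, 0.0628), 24 h 1 (Tnfrsf25, 0.0554), 24 h 2 (Cysltr2, 0.0677) and 24 h 3 (Cysltr2, 0.0599, and Tmem170, 0.0546). Chrna3 lost it without 4 of the 9, and Osr1 and Rhbdf2 without 7.

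In total 477 of 18172 brain genes changed at 24 h (219 higher, 258 lower, edgeR), and 22.2% had groups that do not overlap (10% from chance). The count was 153 without control 1, 228 without control 2, 301 without 0.5 h 2 and 229 without 24 h 1. Of 52 lists 13 passed camera and 0 passed with an estimated correlation, where 3318 single genes had an unadjusted p under 0.05 and fry, a rotation test, passed 2 lists.

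Between 0.5 h and 24 h in the brain, Rbm3 rose by 0.96 ± 0.11 (adjusted p = 0.000562, n = 3 and 3) and Clk1, a kinase of splicing factors, by 0.70 ± 0.08 (0.000562), while Gpr6, a G protein-coupled receptor, fell by 1.95 ± 0.24 (0.000801). Mex3b (0.72 ± 0.15), Nwd2 (0.63 ± 0.10) and the transporter Slco1a4 (0.58 ± 0.08) also rose, and Cysltr2 (−2.77 ± 0.50), Hmgb2 (−1.52 ± 0.26), Txnip, an inhibitor of thioredoxin (−0.97 ± 0.15), and Lingo3 (−0.85 ± 0.15) fell. These 7 lost the call with a library left out. That held for Nwd2 (adjusted p = 0.0624), Slco1a4 (0.0534) and Txnip (0.0646) without 0.5 h 1, and for Txnip without 24 h 1 (0.0518). The call ended for Hmgb2 without 0.5 h 1, 0.5 h 3 or 24 h 3 (up to 0.0795), Cysltr2 without 6 of the 9 (up to 0.0807), Lingo3 without 6 (up to 0.195) and Mex3b without 7 (up to 0.152). Genes of oxidative phosphorylation (1 of 74 lower, median −0.22), chaperones (1 of 25, median −0.20), oligodendrocyte markers (0 of 21, median −0.28) and glucocorticoid targets (0 of 22, median −0.17) passed camera at 5.7e-11, 1.1e-07, 2.3e-05 and 0.0068 (adjusted p = 0.77, 0.68, 0.82 and 0.69 with an estimated correlation). In total 40 genes changed (16 higher, 24 lower, 18.2% not overlapping, 10% from chance), 7 without 0.5 h 1, 16 without 24 h 1 and 91 without 24 h 2. Of the lists 5 passed camera, 9 without 0.5 h 1 and 10 without 24 h 1, and 0 passed with an estimated correlation or by fry, where 2209 genes had an unadjusted p under 0.05.

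In the meninges 0.5 h after irradiation, Per1 fell by 1.33 ± 0.11 (log2, 596 ± 36.1 to 236 ± 30 CPM, adjusted p = 0.0015, n = 3 and 3) and Maff stood at −1.94 ± 0.16 (0.0015, chromosome 15, 79346621 to 79359076, plus strand). Ccn2, a matrix protein induced by mechanical load and growth factors, stood at −1.14 ± 0.11 (0.00184). Foxc2, a transcription factor of meningeal fibroblasts, rose by 0.97 ± 0.09 (0.00178). Of 31 immediate early genes 7 fell and 1 rose (14 lower over the list alone, median −0.61, camera adjusted p = 1.9e-19, adjusted p = 0.17 with an estimated correlation). Glucocorticoid targets fell in 7 of 22 cases (10 over the list alone, median −0.53, camera adjusted p = 1.9e-14, adjusted p = 0.17 with an estimated correlation). Inflammatory genes and targets of NF-kB fell in 4 of 34 cases (10 over the list alone, median −0.43, 1.8e-12, adjusted p = 0.17 with an estimated correlation) and clock genes fell in 5 of 20 (8 over the list alone, median −0.28, 1.9e-11, adjusted p = 0.14 with an estimated correlation). Among ribosomal protein genes 2 of 68 fell, 30 over the list alone (median −0.26, camera adjusted p = 1.1e-20, adjusted p = 0.17 with an estimated correlation).

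Other genes that fell most in meninges at 0.5 h were the cytokine Il6 (−3.58 ± 0.58), the nuclear receptor Nr4a3 (−2.24 ± 0.24), Apol8 (−2.19 ± 0.37), Klrg2 (−1.67 ± 0.32), Socs3, a brake on cytokine signalling (−1.58 ± 0.25), and the stress factor Atf3 (−1.33 ± 0.20). Those that rose most were the zinc finger genes Zfp712 (1.95 ± 0.34), Zfp759 (1.45 ± 0.26), Zfp658 (1.25 ± 0.23), Zfp65 (1.22 ± 0.20) and Zfp324 (1.18 ± 0.19), the chemokine receptor Cxcr6 (1.57 ± 0.27), Kctd21 (1.42 ± 0.28) and the prostaglandin D2 receptor Ptgdr (1.24 ± 0.15). Of the 16 genes named by size Maff and Per1 kept the call whichever library was left out. Nr4a3 and Ptgdr lost it without 0.5 h 2 (adjusted p = 0.056 each), Apol8 without control 2, control 3, 0.5 h 1 or 0.5 h 2 (up to 0.135) and Zfp324 without 4 of the 9 (up to 0.105). The calls of Zfp712 (up to 0.141), Cxcr6 (0.159), Zfp65 (0.13), Socs3 (0.165) and Atf3 (0.109) ended without 5 of the 9 and that of Il6 without 6 (0.124). The calls of Zfp759 (0.159), Zfp658 (0.149) and Klrg2 (0.195) ended without 7, and that of Kctd21 without each of the 9 (0.206). In total 162 of 18542 genes changed (68 higher, 94 lower, 20.8% not overlapping, 10% from chance). The count was 44, 55 and 78 without controls 1, 2 and 3, and 25, 17 and 106 without 0.5 h 1, 2 and 3. With GC content and length corrected, an alternative chosen after seeing the data, 36 were higher and 126 lower. Of 54 lists 16 passed camera and 0 with an estimated correlation, where 2517 genes had an unadjusted p under 0.05 and fry passed 2 lists.

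In the meninges 24 h after irradiation, Mmp3, a protease that cleaves matrix (stromelysin 1), rose by 3.82 ± 0.27 (log2, 2.83 ± 0.36 to 40 ± 10.5 CPM, adjusted p = 6.34e-05, n = 3 and 3, chromosome 9, 7445822 to 7455975, plus strand). Chil1, a chitinase-like protein of macrophages and astrocytes, rose by 2.72 ± 0.18 (18.8 ± 4.68 to 125 ± 22.6 CPM, 6.45e-05, chromosome 1, 134182176 to 134190181, plus strand). The acute-phase protein Saa3 rose from 3 to 195 counts over the group, 68.5 times (counting interval 23.1 to 335, 0.000521, chromosome 7, 46711998 to 46715700, minus strand). Vsig4, a complement receptor of resident macrophages (2.67 ± 0.43), the peptide ligand Apln (2.62 ± 0.33), Dbp, a clock output factor (2.47 ± 0.38), Panx3, a channel of bone and cartilage (2.39 ± 0.37), and Kbtbd8 (2.03 ± 0.42) rose too. Aanat, the rate-limiting enzyme of melatonin synthesis in the pineal gland, fell by 3.47 ± 0.29 (68.5 ± 8.69 to 6.18 ± 1.46 CPM, 0.000502, chromosome 11, 116586432 to 116597680, plus strand). The hour of collection, which the labels do not give, was not tested as a cause of the fall of Aanat. The neutrophil chemokine Cxcl2 (−3.75 ± 0.42), Apol8 (−3.46 ± 0.40), the cytokine Il10 (−2.78 ± 0.49), Rasd1, which glucocorticoids induce (−2.55 ± 0.36), Sytl1 (−2.46 ± 0.36), Iqcn (−4.31 ± 0.91) and Atcayos (−3.27 ± 0.72) fell.

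Antigen presentation genes were lower in meninges at 24 h. Of these, 5 of 11 genes of MHC class II presentation fell and 0 rose (7 lower over the list alone, median −0.66, camera adjusted p = 8.5e-12, adjusted p = 0.047 with an estimated correlation). H2-Eb1 stood at −1.35 ± 0.12 (416 ± 72.9 to 163 ± 10.3 CPM, adjusted p = 0.000171) and Cd74 at −1.33 ± 0.12 (0.000171). Glucocorticoid targets fell in 15 of 22 cases (17 over the list alone, median −1.37, camera adjusted p = 2.6e-34, adjusted p = 0.047 with an estimated correlation). Among these Per1 stood at −1.63 ± 0.12 (6.29e-05) and Klf9, a repressor induced by the hormone, at −1.42 ± 0.15 (0.000546). Immediate early genes fell in 14 of 31 cases and rose in 1 (21 lower over the list alone, median −0.94, camera adjusted p = 2.1e-25, adjusted p = 0.11 with an estimated correlation). Jun stood at −1.37 ± 0.12 (0.000145) and Maff at −2.44 ± 0.16 (6.18e-05). Fos differed among the 24 h libraries, at 237, 50.1 and 73.5 CPM. Inflammatory genes fell in 9 of 34 cases and rose in 2 (13 and 2 over the list alone, median −0.49, camera adjusted p = 1.5e-07, adjusted p = 0.45 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, stood at −1.51 ± 0.10 (6.29e-05) while Saa3 rose. Vdr, the vitamin D receptor, fell by 1.81 ± 0.28 (0.00972), 1 of 2 falls among 9 genes of the vitamin D system (4 over the list alone, median −0.54, camera adjusted p = 0.00029, adjusted p = 0.18 with an estimated correlation).

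Cell cycle genes rose in 10 of 41 cases in meninges at 24 h (16 over the list alone, median 0.54, camera adjusted p = 4.6e-09, adjusted p = 0.7 with an estimated correlation). Of the replication factors, Mcm4 rose by 0.67 ± 0.13 (adjusted p = 0.0121, 0.0581 without control 2) and Mcm5 by 1.28 ± 0.25 (0.017, 0.0643 without control 1). Among markers of border-associated macrophages Lyve1 (0.80 ± 0.11, 0.00212) and F13a1 (0.82 ± 0.12, 0.00295) were 2 of 3 risers of 18. Maf fell by 0.56 ± 0.10 (0.00753), the 1 to do so (4 higher and 1 lower over the list alone, median 0.26, camera adjusted p = 0.019, adjusted p = 0.7 with an estimated correlation). T and NK cell markers fell in 2 of 24 cases, among them Il2rb, of lymphocyte signalling, at −1.27 ± 0.23 (0.00845) (2 over the list alone, median −0.54, camera adjusted p = 0.0017, adjusted p = 0.13 with an estimated correlation). Pineal genes fell in 5 of 13 cases (7 over the list alone, median −0.41, camera adjusted p = 9.8e-05, adjusted p = 0.37 with an estimated correlation). Skeletal muscle markers had a median of −5.03 with 0 of 22 passing (camera adjusted p = 0.0036, adjusted p = 0.95 with an estimated correlation). Muscle RNA differed from piece to piece, with Acta1 from 2.24 to 1030 CPM.

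Clock genes moved in opposite directions in meninges at 24 h. Of 20, 6 rose and 8 fell (camera adjusted p = 0.058). Arntl, which encodes the activator Bmal1, fell by 1.55 ± 0.17 (75 ± 3.88 to 25.6 ± 7.58 CPM, adjusted p = 0.000822) and Nfil3, a repressor of clock output, stood at −2.27 ± 0.19 (0.000194). Per3 rose by 1.44 ± 0.18 (0.00243) along with Dbp. Rbm3 rose by 0.74 ± 0.10 (0.0017), and Cirbp, another cold-inducible RNA-binding protein, stood at −0.09 ± 0.09 (0.594). In total 1561 of 18542 genes changed (736 higher, 825 lower, 28% not overlapping, 10% from chance). The count was 805 without control 1, 727 without control 2, 738 without 24 h 2 and 912 without 24 h 3. Of the 16 genes named by size 13 kept the call whichever library was left out. Kbtbd8 lost it without 24 h 2 (0.0617), Iqcn without control 1 (0.058) and each 24 h library, and Atcayos without control 2 (0.0761), 24 h 1 (0.0563) or 24 h 2 (0.0913). Of 54 lists 15 passed camera and 2 with an estimated correlation.

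**Figure D1:**
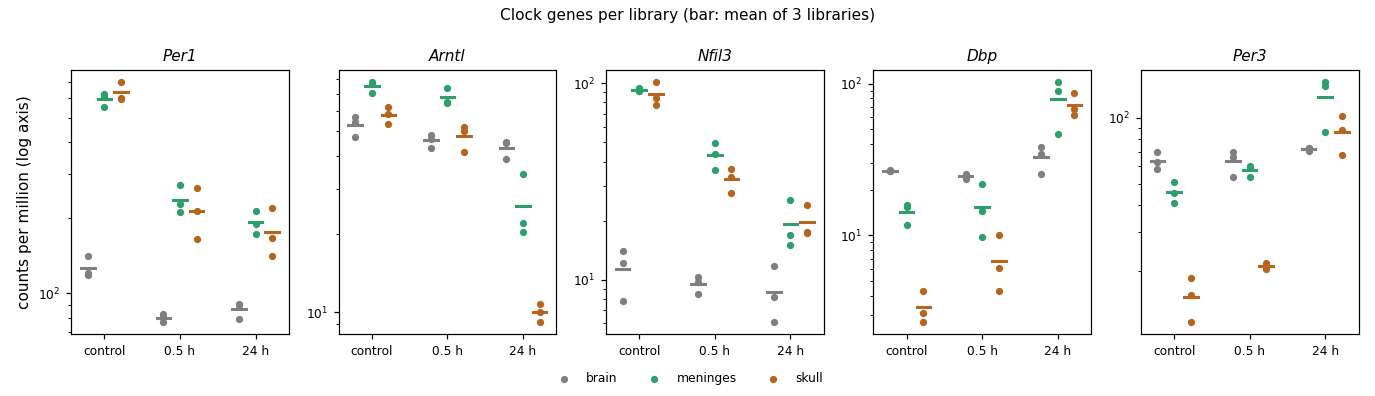
Levels of 5 clock genes (Per1, Arntl, Nfil3, Dbp, Per3) in each library of brain, meninges and skull, in CPM on a log axis, by group (control, 0.5 h, 24 h). Arntl in skull went from 58 ± 4.42 (control) to 9.98 ± 0.807 (24 h).

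Between 0.5 h and 24 h in the meninges, Saa3 rose 67.6 times (counting interval 22.8 to 331, adjusted p = 0.00149, n = 3 and 3). Chil1 rose by 2.96 ± 0.18 (log2, 0.000321), Mmp3 by 3.25 ± 0.26 (0.000589) and Hmox1, which breaks down heme, by 1.11 ± 0.12 (0.00149). In the same libraries Aanat fell by 3.03 ± 0.28 (0.00271). Vsig4 (2.58 ± 0.42) and Dbp (2.37 ± 0.38) rose, and Hmcn2 (−2.90 ± 0.57), Cxcl2 (−2.52 ± 0.41), the glycerol channel Aqp7 (−2.48 ± 0.50) and Il10 (−2.38 ± 0.49) fell. Genes of MHC class II presentation fell in 4 of 11 cases (5 over the list alone, median −0.35, camera adjusted p = 1.2e-08, adjusted p = 0.12 with an estimated correlation), with H2-Ab1 at −0.91 ± 0.12 (0.00582). Glucocorticoid targets fell in 7 of 22 cases (15 over the list alone, median −0.67, 6.8e-20, adjusted p = 0.12 with an estimated correlation), with Map3k6 at −1.01 ± 0.13 (0.00564). Clock genes rose in 8 of 20 cases and fell in 3 (9 and 5 over the list alone, median 0.00, mean 0.25, camera higher, adjusted p = 0.011, adjusted p = 0.42 with an estimated correlation). Nr1d2 stood at 1.33 ± 0.14 (0.00257) and Arntl at −1.40 ± 0.17 (0.00509). Cell cycle genes rose in 5 of 41 cases (16 over the list alone, median 0.54, 1.3e-14, adjusted p = 0.42 with an estimated correlation) and ribosomal protein genes in 9 of 68 (21 over the list alone, median 0.17, 6e-11, adjusted p = 0.42 with an estimated correlation).

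In total 434 meninges genes changed between 0.5 h and 24 h (198 higher, 236 lower, 23.4% not overlapping, 10% from chance). The count was 73, 127 and 120 without 0.5 h 1, 2 and 3, 139 without 24 h 2 and 233 without 24 h 3. With GC content and length corrected 245 were higher and 153 lower. Saa3, Mmp3, Chil1 and Aanat kept the call whichever library was left out. Cxcl2 lost it without 0.5 h 1, 0.5 h 2 or 24 h 2 (adjusted p up to 0.0579), Vsig4 without 5 of the 9 (up to 0.0714), Dbp, Aqp7 and Il10 without 6 (up to 0.116, 0.113 and 0.121) and Hmcn2 without 8 (up to 0.165). Of the lists 24 passed camera and 0 with an estimated correlation, where fry passed 7 lists and 2997 genes had an unadjusted p under 0.05.

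In the skull 0.5 h after irradiation, Myc, a growth regulator, fell by 1.19 ± 0.10 (log2, 76 ± 7.58 to 33.3 ± 2.59 CPM, adjusted p = 0.000392, n = 3 and 3). Cdkn1a stood at −1.23 ± 0.12 (0.000683) and Per1 at −1.56 ± 0.19 (0.00448). The T cell transcription factor Nfatc2 stood at −2.29 ± 0.23 (104 ± 38.6 to 21.3 ± 1.59 CPM, 0.00196) and the interferon-induced chemokine Cxcl9 at −2.18 ± 0.29 (0.00316). Dusp6, a phosphatase that dampens ERK signalling, rose by 0.70 ± 0.08 (0.00182). Immediate early genes fell in 12 of 32 cases and rose in 1 (16 and 1 over the list alone, median −0.63, camera adjusted p = 1.5e-12, adjusted p = 0.64 with an estimated correlation). Fos of this list went from 445 ± 23.7 to 787 ± 51.5 CPM, with each 0.5 h library above each control, and did not pass (0.264). Glucocorticoid targets fell in 9 of 22 cases (14 over the list alone, median −0.71, 8.7e-14, adjusted p = 0.38 with an estimated correlation). Inflammatory genes fell in 11 of 37 (17 over the list alone, median −0.65, 9.5e-14, adjusted p = 0.64 with an estimated correlation), with the adhesion molecule Icam1 at −0.83 ± 0.12 (0.00515). Clock genes fell in 5 of 20 (9 lower and 2 higher over the list alone, median −0.31, 7.1e-08, adjusted p = 0.38 with an estimated correlation), with Nfil3 at −1.43 ± 0.15 (0.00141).

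Ribosomal protein genes fell in 19 of 68 cases in skull at 0.5 h (50 over the list alone, median −0.31, camera adjusted p = 5.6e-18, adjusted p = 0.64 with an estimated correlation). Interferon-stimulated genes had a median of −1.17 with 2 of 41 lower (3 over the list alone, 2.1e-13, adjusted p = 0.8 with an estimated correlation). Erythroid markers had a median of 0.65 with 1 of 29 higher (11 over the list alone, 4.3e-09, adjusted p = 0.8 with an estimated correlation). B cell markers had a median of 0.53 with 3 of 20 higher (7 over the list alone, 3.1e-07, adjusted p = 0.8 with an estimated correlation). By size, Kctd21 (1.75 ± 0.22), Zfp759 (2.13 ± 0.39), Adnp (0.49 ± 0.0194 to 2.13 ± 0.653 CPM), Zfp493 (2.08 ± 0.52), Skint3 (2.06 ± 0.41), Zfp72 (1.87 ± 0.32), the noncoding RNA Lockd (1.83 ± 0.44) and the anion exchanger Slc26a1 (1.60 ± 0.33) rose most. Il6 (−3.13 ± 0.56), Nr4a3 (−2.98 ± 0.40), Ftcd (−2.71 ± 0.50), Apol9b (−2.70 ± 0.60), Mfrp (−2.67 ± 0.63), Gprc5a (−2.47 ± 0.37), the cytotoxic protease Gzmb (−2.41 ± 0.42) and Nfatc2 fell most.

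In total 854 of 17426 skull genes changed at 0.5 h (341 higher, 513 lower, 27.6% not overlapping, 10% from chance). The count was 452 without control 1, 388 without control 3, and 183, 112 and 558 without 0.5 h 1, 2 and 3. Of the 16 genes named by size Kctd21, Gprc5a and Nfatc2 kept the call whichever library was left out. Without 0.5 h 2 the calls of Zfp759 (adjusted p = 0.0617), Adnp (0.083), Skint3 (0.0878), Zfp72 (0.0601), Slc26a1 (0.0841), Il6 (0.0841), Nr4a3 (0.0665), Ftcd (0.0862) and Gzmb (0.054) ended. Without 0.5 h 1 those of Zfp759 (0.054), Adnp (0.0527), Il6 (0.0843), Nr4a3 (0.0521), Ftcd (0.0645) and Gzmb (0.0527) ended. Skint3 (0.0531) and Slc26a1 (0.0565) lost theirs without control 1, and Slc26a1 also without 0.5 h 3 (0.0656). Mfrp lost its call without 4 of the 9 (up to 0.129), Apol9b without 5 (0.151), Lockd without 7 (0.107) and Zfp493 without 8 (0.146). Of 53 lists 16 passed camera and 0 with an estimated correlation, where 3887 genes had an unadjusted p under 0.05 and fry passed 4 lists.

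In the skull 24 h after irradiation, Prg4, the lubricin of joint surfaces, rose by 7.55 ± 0.70 (log2, 6.06 ± 4.11 to 1150 ± 330 CPM, adjusted p = 0.000991, n = 3 and 3, chromosome 1, 150449412 to 150466165, minus strand, sharing 1275 exon bases with Tpr on the opposite strand). Saa3 rose by 6.74 ± 0.47 (4.58e-05) and Arg1, an arginase of repair-associated macrophages, by 6.21 ± 0.47 (0.407 ± 0.108 to 30.8 ± 16.1 CPM, 4.15e-05). The retinoic acid-binding protein Crabp1 (0.142 ± 0.0262 to 4.81 ± 1.73 CPM), Dbp (4.41 ± 0.31), the protease inhibitor Serpina3m (3.63 ± 0.55) and the chromatin protein Hmga2 (3.63 ± 0.71) rose too, as did Mmp3 (3.43 ± 0.34, 0.000282) and its inhibitor Timp1 (1.80 ± 0.22, 0.00109). Garin4 had 0 counts over the 24 h group against 153 in controls, at least 49.4-fold lower (floor of 3 counts over the group, 0.00132). Iqcn (−4.39 ± 0.44), Ftcd (−4.24 ± 0.58), Rasd1 (−3.30 ± 0.22), Ankrd63 (−3.25 ± 0.54), Cyp2t4 (−3.12 ± 0.52), the potassium channel gene Kcnk7 (−3.12 ± 0.50) and Crtam, of cytotoxic lymphocytes (−3.07 ± 0.50), fell.

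**Figure D2:**
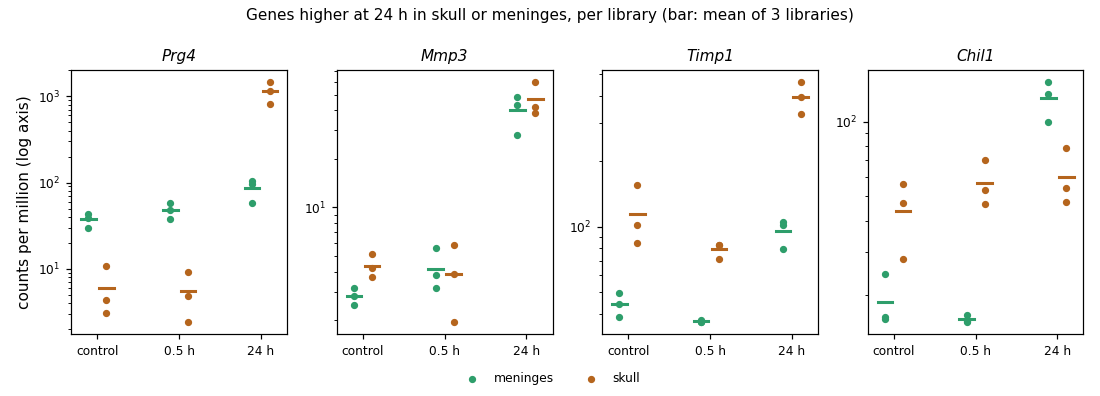
Levels of Prg4, Mmp3, Timp1 and Chil1 in each library of meninges and skull, in CPM on a log axis, by group. Mmp3 went from 2.83 ± 0.36 to 40 ± 10.5 in meninges and from 4.36 ± 0.75 to 46.8 ± 11.7 in skull between control and 24 h.

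Clock genes split in skull at 24 h, where 8 of 20 rose and 8 fell (median −0.21 but mean 0.18, camera adjusted p = 0.94). Arntl fell by 2.54 ± 0.12 (58 ± 4.42 to 9.98 ± 0.807 CPM, adjusted p = 5.25e-07). Npas2, which encodes a partner of Bmal1, stood at −2.02 ± 0.16 (3.61e-05) and Nfil3 at −2.17 ± 0.16 (1.17e-05). Per3 rose by 2.49 ± 0.17 (1.17e-05), Tef, a clock output factor, by 1.88 ± 0.13 (5.97e-06) and Dbp with them. Immediate early genes fell in 24 of 32 cases and rose in 0 (26 over the list alone, median −1.10, camera adjusted p = 3.4e-26, adjusted p = 0.24 with an estimated correlation). Ccn1, a matrix protein, stood at −2.31 ± 0.20 (5.12e-05). Glucocorticoid targets fell in 17 of 22 cases (17 over the list alone, median −1.38, 1.5e-24, adjusted p = 0.22 with an estimated correlation). Cebpd, a transcription factor, stood at −1.58 ± 0.14 (4.57e-05). Genes of the p53 and DNA damage response rose in 7 of 31 cases and fell in 10 (11 and 12 over the list alone, median −0.10, camera adjusted p = 0.019, adjusted p = 0.64 with an estimated correlation). Sesn1 stood at −1.59 ± 0.08 (8.53e-07), Gadd45a at −1.65 ± 0.15 (3.34e-05) and Cdkn1a at −1.25 ± 0.12 (4.43e-05), all induced by p53 in other settings. Inflammatory genes rose in 6 of 37 cases and fell in 10 (camera adjusted p = 0.15). The neutrophil chemokine Cxcl5 stood at 2.74 ± 0.28 (6.89e-05) and the NF-kB inhibitor Tnfaip3 at −1.92 ± 0.19 (0.000169). Genes of collagens and matrix remodelling rose in 3 of 28 cases and fell in 2 (camera adjusted p = 0.54).

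Cholesterol synthesis genes rose in 17 of 23 cases in skull at 24 h and fell in 1 (19 and 1 over the list alone, median 0.79, camera adjusted p = 2.3e-12, adjusted p = 0.22 with an estimated correlation). The enzyme Sqle stood at 1.24 ± 0.14 (adjusted p = 0.000184). Cell cycle genes rose in 10 of 41 (10 over the list alone, median 0.32, 9.6e-05, adjusted p = 0.85 with an estimated correlation), with Ccne2 at 1.06 ± 0.18 (0.00158). B cell precursor markers fell in 8 of 15 cases (10 over the list alone, median −1.18, 2.7e-08, adjusted p = 0.45 with an estimated correlation). Vpreb3 stood at −1.59 ± 0.22 (0.000544) and Bach2 at −1.60 ± 0.17 (0.000151). Erythroid markers fell in 7 of 29 (9 over the list alone, median −0.71, 8.6e-07, adjusted p = 0.85 with an estimated correlation). T and NK cell markers fell in 11 of 26 cases and rose in 1 (15 and 1 over the list alone, median −1.12, 5.1e-05, adjusted p = 0.64 with an estimated correlation), with Cd4 at −1.13 ± 0.20 (0.00208). MHC class II genes fell in 5 of 11 cases (5 over the list alone, median −0.48, 2e-04, adjusted p = 0.64 with an estimated correlation), with H2-Ab1 at −1.24 ± 0.17 (0.00105). Vdr fell by 1.76 ± 0.16 (7.71e-05), 1 of 5 falls among 8 genes of the vitamin D system (5 lower and 1 higher over the list alone, median −0.80, camera adjusted p = 0.0037, adjusted p = 0.42 with an estimated correlation).

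In total 3649 of 17426 skull genes changed at 24 h (1842 higher, 1807 lower, 37.7% not overlapping, 10% from chance), 2223 without 24 h 1. Each of the genes named by size kept the call whichever of the 9 skull libraries was left out. Of 53 lists 15 passed camera and 0 with an estimated correlation, where 5993 genes had an unadjusted p under 0.05 and fry passed 12 lists. Rbm3 rose by 0.69 ± 0.17 (adjusted p = 0.0183, 0.0632 without 24 h 1) and Cirbp fell by 0.65 ± 0.12 (0.00355).

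**Figure D3:**
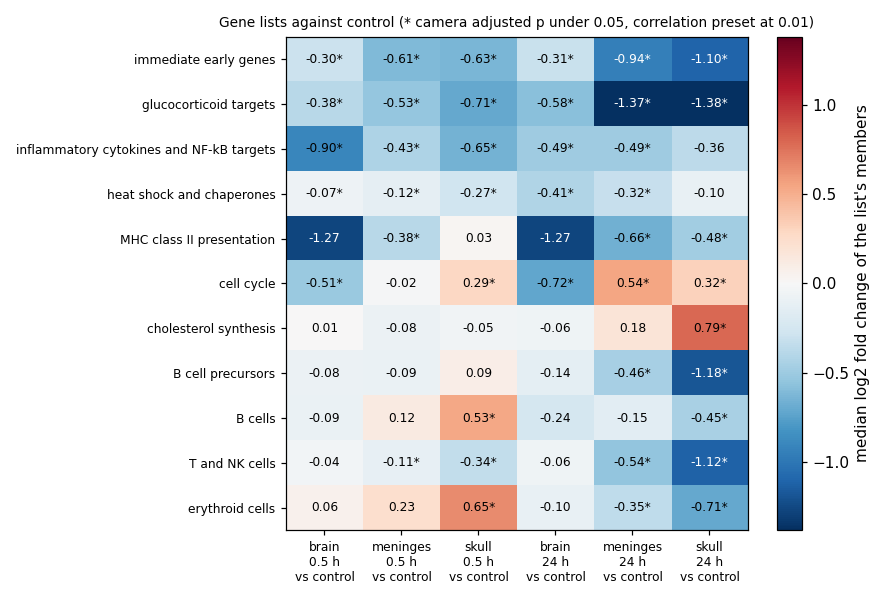
Median log2 fold change of 11 gene lists against control at 0.5 h and 24 h in brain, meninges and skull; stars mark a camera adjusted p under 0.05. Glucocorticoid targets reached −0.58 in brain, −1.37 in meninges and −1.38 in skull at 24 h. In each of these comparisons another split of the labels passed more lists by camera, so a star by itself does not exclude chance.

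Between 0.5 h and 24 h in the skull, Saa3 rose 855 times (3 to 2472 counts, counting interval 292 to 4150, adjusted p = 7.21e-05, n = 3 and 3). Prg4 rose by 7.71 ± 0.71 (log2, 0.00137), Serpina3m by 5.91 ± 0.68 (0.000314), Arg1 by 5.89 ± 0.45 (9.62e-05) and the neutrophil chemokine Cxcl3 by 5.03 ± 0.93 (0.00566). Garin4 was at least 10.3-fold lower (0.0184, floor of 3 counts over the group). Actc1, an actin of striated muscle (−3.91 ± 1.08), Mettl21c, a muscle methyltransferase (−3.51 ± 0.87), Aldh1a7 (−3.40 ± 0.52) and the adhesion molecule Lsamp (−3.26 ± 0.41) fell. Muscle RNA varied between the skull pieces too, with Acta1 at 1160, 624 and 348 CPM in the 0.5 h libraries and 535, 311 and 708 CPM in the 24 h libraries. Erythroid markers fell in 26 of 29 cases (27 over the list alone, median −1.53, camera adjusted p = 4e-24, adjusted p = 0.45 with an estimated correlation). Sptb, a spectrin of red cells, stood at −1.53 ± 0.23 (0.00373). B cell markers fell in 12 of 20 cases (16 over the list alone, median −0.86, 4.2e-13, adjusted p = 0.45 with an estimated correlation), with Ighm at −1.08 ± 0.15 (0.00136). B cell precursor markers fell in 9 of 15 (13 over the list alone, median −1.36, 6.8e-12, adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 23 cases (18 over the list alone, median 0.67, 1.1e-17, adjusted p = 0.2 with an estimated correlation), with Cyp51 at 1.36 ± 0.15 (0.000215). Ribosomal protein genes rose in 22 of 68 (31 over the list alone, median 0.25, 1.1e-08, adjusted p = 0.71 with an estimated correlation). Clock genes rose in 8 of 20 cases and fell in 3 (10 and 5 over the list alone, median 0.44, 2e-05, adjusted p = 0.45 with an estimated correlation). Inflammatory genes rose in 11 of 37 and fell in 5 (12 and 5 over the list alone, median 0.30, 0.00071, adjusted p = 0.78 with an estimated correlation). Ccl2, which draws monocytes, stood at 2.37 ± 0.31 (0.00066).

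In total 2811 skull genes changed between 0.5 h and 24 h (1462 higher, 1349 lower, 37.6% not overlapping, 10% from chance). The count was 1759 without 0.5 h 1, 1676 without 0.5 h 2, 1428 without 24 h 1 and 1491 without 24 h 3. With GC content and length corrected 1943 were higher and 1105 lower. Of the 10 genes named by size 7 kept the call whichever library was left out. Garin4 lost it without 24 h 1 (adjusted p = 0.0564) or 24 h 3 (0.0522). Mettl21c lost it without 0.5 h 1 (0.0688) or 24 h 1 (0.0887) and Actc1 without 7 of the 9 (up to 0.141). Of the lists 15 passed camera and 0 with an estimated correlation, where fry passed 13 lists and 5367 genes had an unadjusted p under 0.05.

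**Figure D4:**
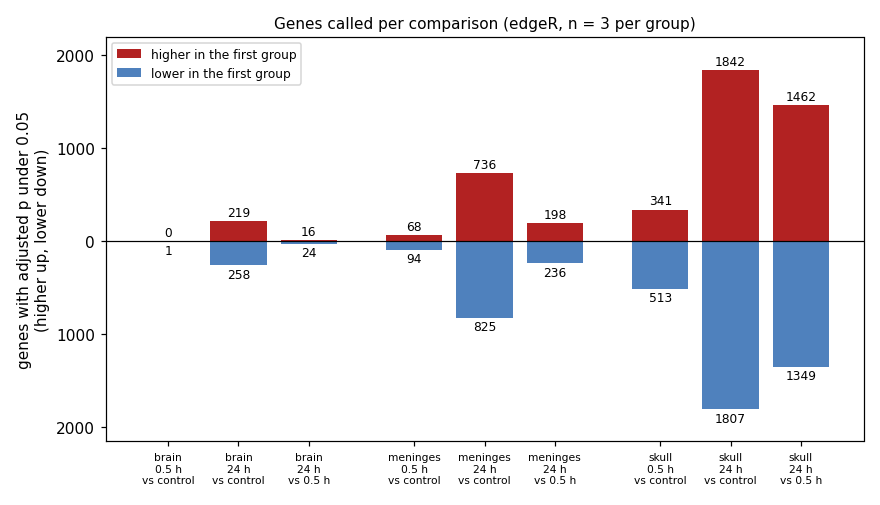
Number of genes called higher and lower in each of the 9 comparisons within a tissue, by edgeR at an adjusted p under 0.05. Counts ran from 1 (brain at 0.5 h) to 3649 (skull at 24 h).

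Differences of log2 fold changes between tissues were tested over 21500 genes of all 27 libraries. At 24 h Prg4 rose more in skull than in brain (difference 6.85 ± 0.62, adjusted p = 1.73e-06) and than in meninges (6.36 ± 0.57, 8.78e-06), as did Crabp1 (6.73 ± 0.76, 9.03e-06, and 5.83 ± 0.64, 2.19e-05). Chil1 rose more in meninges than in skull (−2.26 ± 0.34, 0.00154). Aanat fell in meninges but stood at 0.13 in brain (difference −3.62 ± 0.57, 0.00198). Pineal markers stood at 0.272 CPM in brain controls against 82.3 in meninges controls. The contrast of Aanat thus does not show that pineal tissue responded differently in the 2. At 24 h 283 genes differed between meninges and brain (129 higher in meninges, 154 lower), 1443 between skull and brain (715 and 728) and 136 between skull and meninges (69 and 67). With haemoglobin and mitochondrial genes left out of scaling the first 2 splits turned to 177 and 119 and to 995 and 595, and without a filter to 117 and 87 and to 692 and 438. At 0.5 h 45 genes differed between skull and brain (23 and 22), with Nfatc2 at −2.52 ± 0.25 (1.2e-05). By edgeR 2 differed between meninges and brain, the noncoding RNA Lncppara (1.05 ± 0.17, 0.036) and the repressor Klf13 (−0.62 ± 0.10, 0.036), where 1327 had an unadjusted p under 0.05, DESeq2 called 48 and 5 were the most with a library left out. Between skull and meninges 2 differed, Nfatc2 (−1.88 ± 0.25, 0.00201) and the transcription factor Ets2 (−0.80 ± 0.13, 0.0292), where 1254 had an unadjusted p under 0.05, DESeq2 called 23 and the counts without a library ran from 1 to 5. The calls of Lncppara, Klf13 and Ets2 ended without 16, 18 and 10 of the 27 libraries (adjusted p up to 0.154, 0.143 and 0.141), and the count between meninges and brain was 0 at the lowest.

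The counts of tissue differences moved with a library left out, in which the loss of a replicate may have a part. The 45 genes of skull against brain at 0.5 h became 22 and 20 without brain controls 2 and 3, and 21, 26 and 15 without brain 0.5 h 1, 2 and 3. The count was 21 without skull control 3, and 25 and 13 without skull 0.5 h 1 and 2. The 283 genes of meninges against brain at 24 h became 177 without brain control 1, 156 and 175 without meninges controls 1 and 2, and 165 without meninges 24 h 2. The 136 genes of skull against meninges became 79 without meninges control 2, 80 without meninges 24 h 1, 77 without skull 24 h 1 and 86 without skull 24 h 3.

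Genes called at 24 h were shared between tissues more often than independent lists would be. Meninges and skull shared 430 higher genes (79 if independent) and 491 lower genes (83.8), with 6 opposite. Brain and meninges shared 71 (9.02) and 70 (11.3), with 5 opposite, and brain and skull 71 (22.9) and 83 (25.3), with 21 opposite. In all 3 tissues 46 genes rose at 24 h and 54 fell, out of 15144 tested in each. Rbm3, Nr1d2 and the splicing regulator Tia1 are among the first, and Per1, Maff, Cdkn1a, Sgk1, Tsc22d3, Klf9, Txnip and Errfi1, a brake on EGF receptor signalling, among the second. At 0.5 h meninges and skull shared 37 higher (1.35) and 67 lower genes (2.88), with 0 opposite where edgeR had called 162 and 854. The labels do not say whether the tissues came from the same mice, and the meninges were scraped from the skullcap and held some bone. Shared mice, handling, collection hour or bone may thus add to the overlaps between tissues, and independence does not allow for them. Within a tissue the comparisons at 0.5 h and 24 h share 3 controls, which correlates their errors. The correlation of log2 fold changes was 0.57, 0.52 and 0.48 in brain, meninges and skull against 0.48, 0.51 and 0.50 in simulations without any change. Shared controls alone thus gave a correlation about as high, so the correlation cannot tell whether the changes agree. The covariance was 0.091, 0.142 and 0.147 against a simulated mean of 0.049, 0.099 and 0.057, larger than simulated in each tissue. Called in both were 0 and 1, 55 and 79, and 208 and 321 genes (higher and lower), against 0 and 0.0142, 2.7 and 4.18, and 36 and 53.2 if independent. Called in opposite directions were 0, 1 and 7. In 20 such simulations at most 1 and 0, 1 and 0, and 1 and 3 were called in both. Few genes can be called where none changed, so the simulations do not show how many the shared controls add where genes do change. The 3 controls cannot be divided into 2 sets of 2, so part of the excess may come from the shared controls.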

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

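The tests of technical explanations in the 3 patterns weighed first were chosen only after the results were seen. The exchanges of group labels were planned.

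Clock genes of skull and meninges moved at 24 h: with each of the 20 clock genes counted, the mean log2 level of 15 output and repressor genes minus that of 5 activators went from −0.37 to 1.42 in skull (a move of 1.79) and from −0.11 to 0.88 in meninges (0.99). Collection at another hour of the day may account for this, and would be expected to move the brain as well. The brain index moved by −0.02, from 0.44 ± 0.10 to 0.43 ± 0.16 with groups that were not separated, which cannot tell, because the amplitude of these genes may be smaller in brain. At 0.5 h the index moved by −0.28 in meninges, with groups separated. It moved by −0.25 in skull and −0.09 in brain at 0.5 h, with groups not separated. A change in the mix of cell types stays open too: Arntl and Npas2 averaged −2.28 (SE 0.10) in skull, and the lowest median of 34 marker lists was −1.18, but these 2 genes were picked for their fall and so exclude nothing. Whether irradiation reset clocks near the skull is as open, and groups collected at matched hours could test it.

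At 24 h 6 of 22 glucocorticoid targets were called lower in brain, 15 in meninges and 17 in skull (adjusted p = 0.065, 0.047 and 0.22 with an estimated correlation), and 2 of 31, 14 of 31 and 24 of 32 immediate early genes (adjusted p = 0.67, 0.11 and 0.24 with an estimated correlation), with fewer at 0.5 h. Bias from GC content or length could not be the whole cause in skull at 24 h, where 39 of 40 members called lower (53 tested) stayed lower after a correction that moved the calls of 662 genes. Handling shared alike by both irradiated groups may be part of the cause. If its effect stayed the same over time, it would leave no difference between 24 h and 0.5 h. There 26 of 53 members were lower in skull, 10 of 52 in meninges and 0 of 52 in brain. These counts cannot tell, because an effect of handling at irradiation may change with the time since then. Handling or a collection time that differed from group to group may account for all of it, and the median of −0.58 for glucocorticoid targets in brain at 24 h cannot tell, since the labels give neither. Controls handled like the irradiated mice would be the test.

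In skull at 24 h 8 of 15 B cell precursor and 7 of 29 erythroid markers were called lower (camera adjusted p = 2.7e-08 and 8.6e-07, adjusted p = 0.45 and 0.85 with an estimated correlation). Less marrow in the 24 h pieces would be expected to lower markers of other marrow cells by as much. The mean of B cell precursor markers fell by 1.25 (pooled SD 0.39) relative to that of neutrophil precursors. B cell precursors had the lowest median of the marker lists, and neutrophil precursors were the only marrow list whose mean rose. The contrast was thus picked from extremes of these data and cannot exclude less marrow as the sole cause. Means moved by −1.17 for B cell precursors and −0.77 for erythroid cells. They moved by 0.08 for neutrophil precursors, −0.36 for neutrophils, −0.25 for monocytes, −0.09 for megakaryocytes and −0.05 for stem and progenitor cells. The erythroid fall (SD 0.53 at 24 h) was not tested in this way, and less marrow stays open for it too. Scaling by a few abundant genes could not account for the fall of B cell precursor or erythroid markers, since no other scaling moved the median of all genes in skull at 24 h by more than 0.094. A change in the mix of marrow cells or in the expression of each cell stays open as well, with −1.25 for the contrast of the first test, and bulk RNA does not separate the 2.

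Exchanges of labels gave these counts. Within a tissue 10 splits cannot give a share under 0.05. Splits with as many genes called, the real one included, were 1 in each of the 9 comparisons, with real counts of 1, 477 and 40 in brain, 162, 1561 and 434 in meninges and 854, 3649 and 2811 in skull (0.5 h, 24 h, and 24 h against 0.5 h) and at most 0, 0, 1, 10, 1, 0, 2, 0 and 0 in another split. For lists by camera the splits with as many were 4, 2 and 6 in brain (13, 13 and 5 real, 19, 20 and 10 the highest other), 6, 9 and 1 in meninges (16, 15 and 24, 23, 22 and 19) and 8, 9 and 7 in skull (16, 15 and 15, 28, 24 and 24). Apart from 24 h against 0.5 h in meninges, another split thus passed more lists than the real one. A list that passed camera at the preset correlation is therefore not by itself evidence of a change between the groups. For differences between tissues at 24 h, 1 of 40 regroupings, the real one, reached the 283 genes of meninges against brain (113 the highest other), a share under 0.05. Regrouping removes the effects within each tissue along with their difference, so this share does not by itself show that the effects differ. As many genes came from 5 of 40 for skull against meninges at 24 h (highest other 2480), and at 0.5 h from 14 for meninges against brain (16) and 16 for skull against meninges (178), so this test does not exclude chance for these 3. The highest for skull against meninges kept 0 and 2 of the labels of the irradiated libraries at 0.5 h and 3 and 1 at 24 h. For skull against brain 2 of 40 reached the real 1443 genes at 24 h (highest other 2344) and 2 of 40 the 45 at 0.5 h (231). The 1 other regrouping at each time kept all 3 labels of the irradiated skull libraries and 0 of brain, so it adds the effects of both tissues, and the test tells nothing of chance for these 2.

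These genes had the largest differences between tissues at 0.5 h (log2 difference of fold changes, then the fold change in each tissue). Of 2 genes for meninges minus brain, Lncppara stood at 1.05 (0.51 and −0.55) and Klf13 at −0.62 (−0.73 and −0.12). Of 45 for skull minus brain, Zfp759 stood at 1.88 (2.13 and 0.26), Fam111a at 1.58 (0.77 and −0.81), and Kctd21 at 1.48 (1.75 and 0.28), Zfp780b at 1.18 (1.33 and 0.16), Ccdc77 at 1.17 (0.84 and −0.32). Lower there were Nr4a3 at −2.68 (−2.98 and −0.29), Nfatc2 at −2.52 (−2.29 and 0.24), the GABA transporter Slc6a11 at −2.0 (−1.72 and 0.29), Cnih2 at −1.39 (−1.41 and −0.02) and the choline kinase Chka at −1.26 (−1.45 and −0.19). Of 2 for skull minus meninges, Nfatc2 stood at −1.88 (−2.29 and −0.39) and Ets2 at −0.80 (−0.79 and 0.04). Calls ended with a library left out for Lncppara (16 of 27, adjusted p up to 0.154), Klf13 (18, 0.143), Zfp759 (9, 0.105), Kctd21 (8, 0.0951), Zfp780b (8, 0.111), Ccdc77 (9, 0.101), Slc6a11 (6, 0.109), Cnih2 (10, 0.132) and Ets2 (10, 0.141).

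At 24 h, of 283 genes for meninges minus brain, Cdk1 stood at 4.74 (0.54 and −4.15), Uhrf1, which maintains DNA methylation, at 3.25 (1.44 and −1.78), Top2a, a topoisomerase of dividing cells, at 3.14 (0.88 and −2.25), Apln at 2.84 (2.62 and −0.23), and Kctd11 at 2.77 (1.66 and −1.11). Lower there were Atcayos at −5.60 (−3.27 and 2.31), Aanat at −3.62 (−3.47 and 0.13), Apol8 at −3.27 (−3.46 and −0.23), the synaptic gene Arc at −2.71 (−0.92 and 1.78) and Chrna3 at −1.99 (−0.40 and 1.56). Aanat is a gene of the pineal gland, whose markers stood at 0.272 CPM in brain controls and 82.3 in meninges controls. Of 1443 for skull minus brain, Prg4 stood at 6.85 (7.55 and 0.70), Ccl2 at 6.73 (1.87 in skull), Crabp1 at 6.73 (5.0 and −1.71) and Ccl7, a monocyte chemokine, at 6.45 (2.19 in skull). Lower there were Atcayos at −3.94 (−1.62 and 2.31), Arc at −2.94 (−1.16 and 1.78), Lsamp at −2.93 (−2.81 and 0.11), Ankrd63 at −2.89 (−3.25 and −0.38) and Cecr2 at −2.84 (−2.10 and 0.73). Ccl2 and Ccl7 did not pass the filter in brain alone. Of 136 for skull minus meninges, Prg4 stood at 6.36 (7.55 and 1.20), Crabp1 at 5.83 (5.0 and −0.80), the tubulin Tubb3 at 3.30 (1.91 and −1.37), Il1rl1, the receptor of interleukin 33, at 2.24 (2.57 and 0.34). Lower there were Ntm at −2.54 (−2.12 and 0.44), Myh7b at −2.48 (−2.57 and −0.06), the cohesin gene Rec8 at −2.47 (−1.97 and 0.52), Chil1 at −2.26 (0.45 and 2.72) and Kcnd3 at −2.20 (−2.34 and −0.13). Without brain control 1 the calls of Top2a (adjusted p = 0.173), Kctd11 (0.15), Ccl2 (0.586) and Ccl7 (0.0819) ended. Without skull 24 h 1 those of Lsamp (0.134) and Kcnd3 (0.06) ended, and without meninges 24 h 1 those of Tubb3 (0.0566) and Rec8 (0.119). Arc against meninges lost its call without meninges control 1 (0.0989) and Il1rl1 without skull 24 h 3 (0.118). Libraries that ended calls numbered 23 of 27 for Top2a, 7 for Kctd11, 6 for Arc, 3 for Ccl2, 1 for Ccl7, 21 for Lsamp, 2 for Tubb3, 18 for Il1rl1, 8 for Rec8 and 1 for Kcnd3.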

How the results depend on the processing

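Of the alternatives below, the correction for GC content and length and the thinning of brain control 1 were chosen only after the result was seen. The others were planned. No log2 fold change of a named gene called in either fit turned sign under an alternative. Over the named genes and alternatives, libraries left out included, 12473 cases kept their status as called or not. A call was gained in 341 and lost in 1239, and the size of the fold change was not compared. Counts moved by over 1.5 times as follows (0.5 h, 24 h and 24 h against 0.5 h are taken in turn). Brain genes at 0.5 h (1) were 100 without a filter, 14 by DESeq2, 3 in the fit of 27 libraries and 0 with the correction for GC content and length, where edgeR with the filter called 1 and limma-voom 1. Thinning brain control 1 left 1. Brain genes at 24 h (477) were 1214 without a filter, 807 by DESeq2 and 301 from 2 groups alone, and thinning brain control 1 moved them less, to 448. Brain genes for 24 h against 0.5 h (40) were 438 without a filter, 225 by DESeq2 and 25 from 2 groups. Meninges genes at 0.5 h (162) were 261 without a filter, 67 with a replicate block (21 higher, 46 lower), 295 by limma-voom, 511 by DESeq2 and 371 in the fit of 27 libraries. At 24 h (1561) they were 1030 with the block and 902 from 2 groups, and for 24 h against 0.5 h (434) 241 with the block and 947 by DESeq2. Skull genes at 0.5 h (854) were 560 with the block, 1441 by DESeq2 and 530 from 2 groups. Lists by camera with an estimated correlation were 2, 0 and 0 in brain, 0, 2 and 0 in meninges and 0, 0 and 0 in skull, and by fry 1, 2 and 0, 2, 8 and 7, and 4, 12 and 13. Lists for 24 h against 0.5 h were 9 in brain without a filter and 9 with the block, and 23 in skull without a filter.

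Differences between tissues moved too. At 0.5 h those of meninges against brain (2) were 1 with RLE scaling, 1 with haemoglobin and mitochondrial genes left out of scaling, 0 without a filter, 0 with the block and 48 by DESeq2. Those of skull against brain (45) were 27 with the block and 247 by DESeq2, and those of skull against meninges (2) were 1 with the block and 23 by DESeq2. At 24 h those of meninges against brain (283) were 833 by DESeq2, those of skull against brain (1443) 2195 by DESeq2, and those of skull against meninges (136) 76 with the block and 423 by DESeq2. With haemoglobin and mitochondrial genes left out of scaling the higher and lower counts became 177 and 119 for meninges against brain and 995 and 595 for skull against brain at 24 h, and 27 and 14 for skull against brain at 0.5 h. Without a filter they became 117 and 87, 692 and 438, and 28 and 14. The majority of calls turned from higher to lower or back in further cases (higher and lower in turn). Meninges for 24 h against 0.5 h (198 and 236) had 245 and 153 with the correction for GC content and length and 329 and 292 by limma-voom. Skull at 24 h (1842 and 1807) had 1776 and 1847 with RLE scaling, 1951 and 2036 by DESeq2, 1506 and 1573 from 2 groups and 1908 and 2006 in the fit of 27 libraries. Skull for 24 h against 0.5 h (1462 and 1349) had 1396 and 1404 with RLE scaling, 1594 and 1624 by DESeq2 and 1396 and 1512 in the fit of 27 libraries. Skull against brain had 1123 and 1072 by DESeq2 at 24 h and 10 and 17 with the block at 0.5 h, and meninges against brain at 24 h had 417 and 416 by DESeq2. Skull against meninges at 24 h (69 and 67) had more lower than higher under each of its 5 alternatives apart from libraries left out, such as 58 and 60 with RLE scaling and 195 and 228 by DESeq2. The block rests on replicate numbers, and correlations of residuals between libraries of the same number ran from −0.396 to 0.117 within a tissue (1 of 27 over 0.1) and from −0.0503 to 0.0942 across tissues (0 of 27). Without any scaling factor the median of all genes moved by 0.092 in meninges at 24 h, 0.1 in skull at 0.5 h and 0.094 in skull at 24 h.

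Leaving out each library in turn gave from 0 to 9, 153 to 437 and 7 to 91 genes in brain, 17 to 172, 727 to 1376 and 73 to 476 in meninges, and 112 to 869, 2223 to 3667 and 1428 to 3315 in skull. Lists ran from 7 to 15, 9 to 17 and 5 to 10 in brain, 13 to 19, 15 to 21 and 17 to 26 in meninges, and 14 to 19, 14 to 20 and 15 to 21 in skull. Differences ran from 0 to 5 (meninges against brain), 13 to 53 (skull against brain) and 1 to 5 (skull against meninges) at 0.5 h, and from 156 to 323, 986 to 1511 and 77 to 153 at 24 h. For 24 h against control, each such gene count was below that of all libraries in brain (477) and in meninges (1561). Loss of a replicate alone may lower a count, so a lower count need not point to an unusual library.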

Other observations

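The zinc finger test below was chosen only after the result was seen.

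Further lists moved in parts of the series. Astrocyte markers fell in 6 of 17 cases in skull at 24 h (7 over the list alone, median −0.69, camera adjusted p = 0.0025, adjusted p = 0.24 with an estimated correlation), led by genes that other cells share. Glul, which makes glutamine, stood at −1.26 ± 0.11 (2.68e-05) and Fgfr3, of bone growth, at −0.65 ± 0.09 (0.000744). Markers of meningeal fibroblasts fell in 4 of 25 cases in skull at 24 h (4 over the list alone, median −0.54, camera adjusted p = 0.014, adjusted p = 0.85 with an estimated correlation), with Foxc1, a transcription factor of skull and meninges, at −0.92 ± 0.13 (0.000753). Chaperones fell in 4 of 25 cases in skull at 0.5 h (6 over the list alone, median −0.27, camera adjusted p = 7.9e-05, adjusted p = 0.8 with an estimated correlation), with Dnajb4 at −0.52 ± 0.10 (0.014, 0.0811 without 0.5 h 2). In brain at 24 h hypoxia targets fell in 1 of 25 cases (6 over the list alone, median −0.20, camera adjusted p = 1e-04, adjusted p = 0.47 with an estimated correlation), Pfkfb3, a regulator of glycolysis, at −0.45 ± 0.08 (0.00705). Adipocyte markers fell in 1 of 13 cases in meninges at 24 h (1 over the list alone, median −0.89, camera adjusted p = 0.00023, adjusted p = 0.56 with an estimated correlation), the lipase Pnpla2 at −0.87 ± 0.11 (0.00126).

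Zinc finger genes, often expressed at low levels, were taken by symbol alone (Zfp, Zkscan or Zscan followed by a number), so the set may mix genes of different function. They were called higher more often than other genes in 5 of the 6 comparisons with control. The 0.5 h and 24 h comparisons of a tissue share the same 3 controls, so these 5 are not independent of each other. They were higher in 38 of 387 cases and lower in 0 in brain at 24 h (Fisher p = 8.3e-24), 26 of 390 and 0 in meninges at 0.5 h (2.1e-26), 66 and 8 in meninges at 24 h (7e-24), 49 of 380 and 5 in skull at 0.5 h (3.6e-26) and 88 and 26 in skull at 24 h (1.1e-12), with medians of 0.25, 0.27, 0.25, 0.26 and 0.26. In brain at 0.5 h 0 of 387 were higher, where edgeR called 1 gene in all. Between 0.5 h and 24 h they were higher in 3 of 387 cases in brain (0.0044) and in 2 of 390 in meninges (0.45). In skull they were higher in 6 of 380 cases and lower in 18, against 1456 of 17046 other genes higher, which is fewer than for other genes (1.7e-08). Medians between 0.5 h and 24 h were 0.10 in brain, −0.01 in meninges and −0.04 in skull. Low values in the shared controls could therefore give the rise at both times in meninges and skull. Bias from GC content or length could not be the whole cause in skull at 24 h, where 85 of the 88 stayed higher after correction, nor in meninges at 24 h (53 of 66) or skull at 0.5 h (43 of 49). In brain at 24 h 28 of 38 and in meninges at 0.5 h 12 of 26 stayed, while the medians went from 0.25 to 0.21 and from 0.27 to 0.21. Many genes of this set lie in clusters of close relatives, so reads may have been shared among them by the count, and neighbours are not independent in the Fisher test.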
